A study of Mus musculus with 250 samples.

How the data were processed

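Whole-tissue RNA of female FVB mice was measured in breast, liver, spleen, blood cells and thymus on whole-genome mouse GeneChip arrays of Affymetrix, 250 arrays in all. In each of the 5 tissues there were 25 arrays of tumor-bearing mice and 25 arrays of control mice, and each sample's label named the age- and cage-matched mouse of the other group, which gave 25 matched pairs per tissue. RNA was extracted with Trizol and turned into biotin-labelled cRNA with a one-cycle labelling kit for 3 prime arrays. The values deposited by the authors are linear probe set intensity, already summarised and normalized. The summarisation and normalization methods are not given in the sources used here. All values of the 45101 probe sets were positive, between 5.17 and 47198, with none missing. The array medians lay close together within a tissue and apart between tissues (median of the array medians 63.4 in breast, 47.3 in liver, 106 in spleen, 25.2 in blood and 129 in thymus). The tissues therefore look as if they were normalized separately, so levels are compared within a tissue and only differences between matched mice are compared between tissues. For arrays, the number of arrays limits the precision.

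Intensities under the 5th percentile of all values (11.3) were raised to it, and log2 was taken. Of the probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were unnamed here. Symbols were taken from the mouse annotation GRCm38.p6, with 34754 matched by their Entrez gene number and 204 kept as listed. No genome coordinates are given, because the sources used here name no genome build for the array. For each gene the probe set with the highest mean over all arrays was used, which gave 18194 genes. Probe sets with no symbol or several were tested separately, except 51 control probe sets of the array, which were left out.

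In each tissue, tumor-bearing and control mice were compared with limma 3.58.1 in R 4.3.3, with the matched pair as a block, empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes of the tissue. A gene was called at an adjusted p under 0.05, and "rose" and "fell" below refer to the tumor-bearing mouse relative to its matched control. Changes are log2 differences with their standard error over pairs. A fit across liver, spleen, blood and thymus tested whether a gene's change differed between these tissues (200 arrays, block for the pair within the tissue). Breast was kept out of that fit because its tumor-bearing samples hold the tumor itself. Fits and tables otherwise used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The test was tried on simulated data of the same size with 200 changed genes, all above the median level. It recovered between 44.8 and 79.1 percent of changes of 0.5 on the log2 scale, depending on the tissue. Of changes of 1 it recovered between 87.9 and 98.5 percent. Between 1.75 and 7.01 percent of its calls there were false. The simulated genes varied independently of each other with normal spread. Recovery of dimmer genes and false calls among correlated genes were therefore not tried.

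The comparisons, the alternatives, the rule for named genes and 37 lists of genes (cell types, pathways and tissue markers) were fixed before the data were examined. The lists held 669 genes, of which 621 were measured. Each list was tested in each tissue with camera from limma with a preset correlation between genes of 0.01, and the 185 tests were adjusted together. Camera asks whether the members of a list moved further than the other genes. It was repeated with a correlation estimated from the data, and that p is given beside each call. A sign-flip test was added after seeing the data. It asks whether the mean of a list moved at all, by flipping the sign of within-pair differences at random 100000 times, two-sided, with 1e-05 as the smallest p it can give. For each list, the members called are also counted with p adjusted over the list alone. The rule for named genes took Erbb2, the 10 higher and 10 lower genes with the largest change among those called and moved in the same direction in at least 20 of the 25 pairs, up to 3 called members with the smallest p of each list that passed, and up to 10 genes called in the same direction in most tissues. It named 211 genes. A gene outside that rule is pointed out as chosen after its values were seen. Changes of lists were compared between tissues by permuting the tissue labels over all pairs, with 257 tests adjusted together. This treats the tissues as independent, as does the fit across 4 tissues, so a sign-flip test within linked mice was added after seeing the data.

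The matched pairs come from the labels. After the mean of each group in the tissue was removed, the median correlation between the mice of a pair was 0.08 in breast, 0.31 in liver, 0.15 in spleen, 0.22 in blood and 0.25 in thymus, against values between -0.02 and 0.01 for other pairings. It lay above 0.1 in 11 of 25 pairs in breast, 20 in liver, 14 in spleen, 15 in blood and 16 in thymus. The tumor-bearing mouse correlated best with its own partner in 5, 13, 6, 4 and 5 of 25 pairs in the same order.

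Mice of different tissues were linked through the number they share in their labels, which was assumed to mark the same mouse (24 of the 25 blood pairs could be linked). Correlations across mice used within-pair differences and are given as Pearson's r and Spearman's rho with two-sided permutation p. Sample numbers fall into an earlier series (10 pairs) and a later series (15 pairs), taken here as batches. Spleen and thymus were hybridised together on 1 set of plates (24 pairs each), liver and blood on another (24 pairs each) and breast on another (25 pairs). The remaining pair of each of the other 4 tissues shared the breast plate, so tissue and plate cannot be told apart, while both mice of a pair shared the set of plates.

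The alternatives fixed in advance were an offset of 16 in place of the floor, quantile normalization, median centring, the mean of all probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at, leaving out genes under the median level, trend and robust moderation, array weights, a plain paired t-test per gene, an adjusted p under 0.01, no replicate block, each batch alone, and leaving out pairs on another plate or with differing date parts in their array names. After seeing the data, 18 arrays were found to correlate under 0.95 with the median array of their own tissue (log2, all probe sets). These are called the outlying arrays, and leaving out the 16 pairs that hold them (109 of 125 pairs kept) was added as an alternative, as was leaving out breast pairs 1 and 2. Leaving out the 6 blood pairs with an array rich in hepatocyte transcripts (list mean over 3 above the median of blood arrays) was also added. Another 8 marker lists, of organs near the sampled tissues, were added after these array correlations were seen. No array was moved to another group or relabelled, and none was left out of the values given as main results.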

Results

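Gene expression was profiled in a mouse model of Her2/Neu breast cancer to ask how tumor-bearing mice differ from matched controls in the tumor tissue and in distant tissues. Tumor-bearing mice carried both the MMTV-rtTA and TetO-NeuNT transgenes, so that doxycycline switches on NeuNT, the activated form of the rat homologue of the receptor tyrosine kinase gene Erbb2, in mammary epithelium. Controls were littermates that carried TetO-NeuNT alone. All mice drank doxycycline (2 mg/mL, with 5% sucrose) from 8 weeks of age, and tissue was taken when the tumor reached 1 cm. The data comprise 25 matched pairs in each of breast, liver, spleen, blood cells (blood without its plasma) and thymus. Changes below are log2 differences, tumor-bearing minus control, given as mean ± SE over 25 pairs unless another n is stated, with p from limma and adjusted by the method of Benjamini and Hochberg.

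The mouse Erbb2 probe set was examined first, since the transgene encodes the rat form of this receptor. Whether this probe set also detects the rat transcript is not known from the labels. Its signal therefore cannot be assigned to the mouse gene or to the transgene. In breast the Erbb2 signal was 8.41 ± 0.36 (SD, n = 25) in tumor-bearing mice against 7.13 ± 0.59 in controls, a 2.43-fold rise (1.28 ± 0.15, higher in 23 of 25 pairs, permutation p = 1e-05, the smallest these permutations can give, adjusted p = 5e-05 over 5 tissues). The signal did not pass the test in liver (-0.09 ± 0.05, adjusted p = 0.198), spleen (-0.21 ± 0.14, adjusted p = 0.25), blood (0.03 ± 0.09, adjusted p = 0.738) or thymus (0.11 ± 0.16, adjusted p = 0.642). Spleen pairs 13 and 21 were at -2.77 and -1.74, and without the outlying arrays, which include the controls of both pairs, the spleen value was -0.03 ± 0.06 (23 pairs). The pairs with lower Erbb2 in the tumor-bearing mouse were breast pairs 1 and 2 (-0.69 and -0.61), and the other 23 pairs lay between 0.25 and 2.70.

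**Figure D1:**
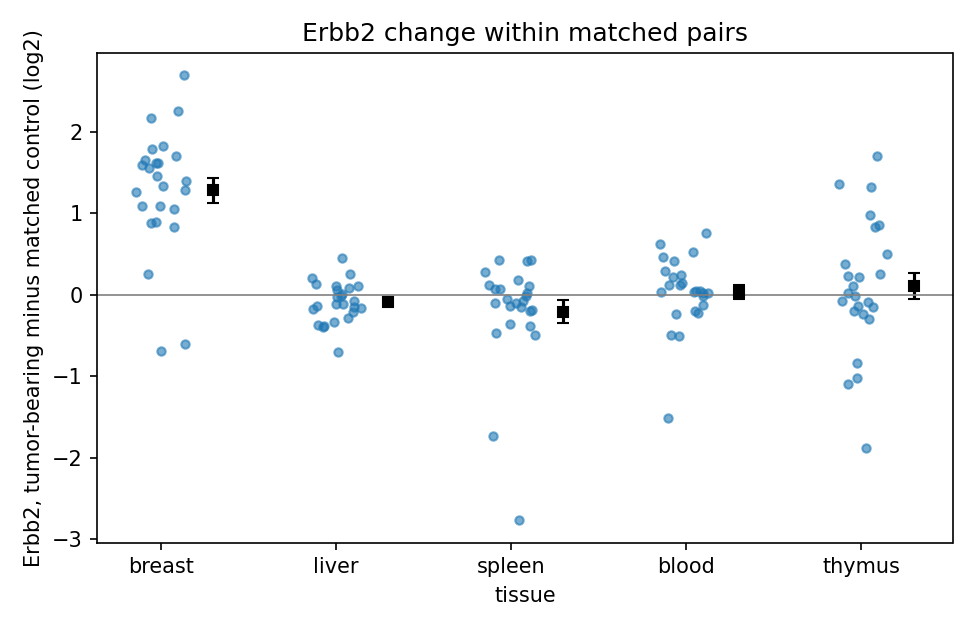
Within-pair log2 difference of the Erbb2 signal (tumor-bearing minus control) by tissue, where each point is 1 of 25 pairs and the black square with its bar is the mean ± SE. The breast mean is 1.28 with 23 of 25 pairs above 0, and the means of the other tissues lie between -0.21 and 0.11.

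The cell cycle, luminal epithelial and extracellular matrix lists rose in tumor-bearing breast, and the adipocyte, skeletal muscle, T cell, B cell and NK lists fell. None of these passed with an estimated correlation (adjusted p of 0.406 or more), and the T cell and B cell lists fell in the later batch alone. Whole tumor-bearing tissue was compared with whole control breast. A change in the mix of cells and a change of expression per cell therefore cannot be told apart in breast. Mmp13, a collagenase, rose 27.3-fold (4.77 ± 0.40) and Col11a1, a fibrillar collagen, rose 21.8-fold (4.45 ± 0.30). Among the genes with the largest rises were also Dmp1 (4.10 ± 0.30), Tc2n (4.04 ± 0.31), the granzymes Gzmd (3.95 ± 0.45) and Gzme (3.85 ± 0.39), the kallikrein Klk6 (3.94 ± 0.32), Chl1 (3.90 ± 0.25) and the neutrophil granule gene Pglyrp1 (3.86 ± 0.24). Among the genes with the largest falls were the carboxylesterases Ces1d (-5.03 ± 0.42) and Ces1f (-4.93 ± 0.38), the leptin gene Lep (-4.52 ± 0.35), the lipid droplet gene Cidec (-4.47 ± 0.39), the retinol carrier Rbp4 (-4.55 ± 0.42), Tmem45b (-4.80 ± 0.45), Orm1 (-4.69 ± 0.38), Aldh1a7 (-4.53 ± 0.41), Cyp2e1 (-4.44 ± 0.43) and Ucp1 (-4.58 ± 0.60), the uncoupling protein of brown fat. In all, 5456 of 18194 genes rose and 5873 fell (5646 and 6329 in the 24 pairs without the outlying arrays, and 5586 and 6040 without breast pairs 1 and 2).

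Of the 27 measured cell cycle genes, 27 rose (27 adjusted over the list alone, list mean 1.51 ± 0.14, adjusted p = 5.01e-13, and adjusted p = 0.406 with an estimated correlation), with Rrm2 (2.38 ± 0.19), Cdk1 (2.36 ± 0.21) and Bub1 (2.21 ± 0.18) as examples. The list of ErbB receptors, ligands and ERK feedback genes had 17 of 20 members higher (17 adjusted over the list alone, list mean 1.29 ± 0.10, adjusted p = 4.8e-07, and adjusted p = 0.313 with an estimated correlation). Its examples are the ligand gene Hbegf (3.32 ± 0.24), the ERK-induced transcription factor Etv5 (2.85 ± 0.21) and the ERK phosphatase gene Dusp6 (2.04 ± 0.15). Luminal epithelial genes rose in 14 of 20 members and fell in 4 (14 and 4 adjusted over the list alone, list mean 1.03 ± 0.12, adjusted p = 0.00129, and adjusted p = 0.491 with an estimated correlation). Cldn7 (3.01 ± 0.25), Spint1 (2.48 ± 0.22) and Epcam (2.19 ± 0.18) rose, while the hormone receptor genes Pgr (-2.24 ± 0.28) and Esr1 (-1.66 ± 0.14), chosen after their values were seen, fell. Extracellular matrix genes rose in 13 of 24 members and fell in 2 (13 and 2 adjusted over the list alone, list mean 0.80 ± 0.15, adjusted p = 0.00355, and adjusted p = 0.721 with an estimated correlation), with Tnc (3.53 ± 0.33), Timp1 (3.26 ± 0.27) and Thbs1 (2.70 ± 0.26) among those that rose. Immediate early and heat shock genes rose in 12 of 19 members and fell in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.00162, and adjusted p = 0.488 with an estimated correlation). Ier3 (3.18 ± 0.23) and Ier2 (1.45 ± 0.15) rose. ER stress and amino acid response genes rose in 11 of 17 and fell in 3 (11 and 3 adjusted over the list alone, adjusted p = 0.00484, and adjusted p = 0.491 with an estimated correlation). Trib3 (2.00 ± 0.17) and the chaperone gene Hspa5 (0.97 ± 0.10) rose. Neutrophil granule and surface genes rose in 9 of 18 and fell in 1 (9 and 1 adjusted over the list alone, list mean 0.81 ± 0.10, adjusted p = 0.0163, and adjusted p = 0.573 with an estimated correlation). S100a8 (2.56 ± 0.29) and Padi4 (1.49 ± 0.18) rose.

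The adipocyte, brown fat and both fatty acid lists fell, while cholesterol synthesis genes went both ways and did not pass as a list (6 of 18 members higher and 9 lower, adjusted p = 0.39). All 16 measured adipocyte genes fell (16 adjusted over the list alone, list mean -3.19 ± 0.28, adjusted p = 2.23e-09, and adjusted p = 0.426 with an estimated correlation). The triglyceride lipase gene Pnpla2 (-2.40 ± 0.17) and the insulin-responsive glucose transporter gene Slc2a4 (-2.77 ± 0.21) fell. Fatty acid synthesis genes fell in 13 of 15 members (13 adjusted over the list alone, list mean -2.02 ± 0.17, adjusted p = 3.36e-06, and adjusted p = 0.426 with an estimated correlation). Mlxipl (-3.65 ± 0.27), Acss2 (-3.27 ± 0.25) and the acetyl-CoA carboxylase gene Acaca (-2.61 ± 0.19) fell. Fatty acid oxidation and PPAR alpha target genes fell in 13 of 16 and rose in 1 (13 and 1 adjusted over the list alone, list mean -1.58 ± 0.15, adjusted p = 4.33e-05, and adjusted p = 0.436 with an estimated correlation). Cpt2 (-2.38 ± 0.18) and Acadm (-2.06 ± 0.16) fell. Brown fat genes fell in 7 of 9 (7 adjusted over the list alone, adjusted p = 0.00628, and adjusted p = 0.488 with an estimated correlation). Cox8b (-4.27 ± 0.43) and Otop1 (-4.14 ± 0.41) fell. Skeletal muscle genes fell in 17 of 17 (17 adjusted over the list alone, list mean -2.65 ± 0.69, adjusted p = 0.00335, and adjusted p = 0.721 with an estimated correlation). Eno3 (-2.80 ± 0.58), Tcap (-2.74 ± 0.62) and the myoglobin gene Mb (-2.55 ± 0.56) fell. Endothelial genes fell in 11 of 14 and rose in 1 (12 and 1 adjusted over the list alone, list mean -0.90 ± 0.12, adjusted p = 0.00104, and adjusted p = 0.592 with an estimated correlation). Cdh5 (-1.39 ± 0.15), Robo4 (-1.33 ± 0.14) and the VEGF receptor gene Kdr (-1.29 ± 0.13) fell.

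T cell genes fell in 16 of 17 members (16 adjusted over the list alone, list mean -1.26 ± 0.30, adjusted p = 0.00194, and adjusted p = 0.71 with an estimated correlation), B cell genes in 14 of 16 (14 adjusted over the list alone, list mean -1.32 ± 0.32, adjusted p = 0.00993, and adjusted p = 0.721 with an estimated correlation) and NK and cytotoxic genes in 10 of 13 (10 adjusted over the list alone, list mean -0.86 ± 0.14, adjusted p = 0.00513, and adjusted p = 0.592 with an estimated correlation). Examples are Cd3g (-2.28 ± 0.42), Cd28 (-1.97 ± 0.39), Ebf1 (-2.34 ± 0.23), Cd79b (-2.09 ± 0.44), Gzma (-1.78 ± 0.19) and Tbx21 (-1.03 ± 0.13). In the 10 pairs of the earlier batch alone the T cell and B cell list means were both 0.06, against -2.14 and -2.25 in the 15 pairs of the later batch. The NK (-0.27 against -1.25), progenitor (-0.36 against -0.71), extracellular matrix (0.46 against 1.02) and skeletal muscle lists (-1.80 against -3.22) did not pass in the earlier batch alone either. Skeletal muscle genes lay more than 3 above their median in 5 breast arrays, B cell genes in 2 and T cell genes in 1, all controls. Haematopoietic progenitor genes fell in 9 of 14 and rose in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.03, and adjusted p = 0.491 with an estimated correlation). Cebpa (-2.38 ± 0.20) and Gata2 (-0.94 ± 0.10) fell. Milk genes (8 of 13 higher and 2 lower, adjusted p = 0.191) and interferon response genes (adjusted p = 0.677) did not pass as lists. Basal and myoepithelial genes fell in 6 of 12 members and rose in 1 (6 and 1 adjusted over the list alone, list mean -0.85 ± 0.16, adjusted p = 0.0544, and adjusted p = 0.7 with an estimated correlation). That list passed the sign-flip test (adjusted p = 4.6e-05) and camera with no replicate block (adjusted p = 0.0478). With genes under the median level left out, 7 lists no longer passed camera, although most of their means did not shrink. The means were 1.57 for neutrophil, 0.80 for extracellular matrix, 0.55 for ER stress, -0.63 for progenitor, -0.87 for T cell, -1.66 for B cell and -1.92 for NK genes, against 0.81, 0.80, 0.55, -0.57, -1.26, -1.32 and -0.86 with all genes. The neutrophil list mean of 0.75 in the later batch alone did not pass either. The 3 prime to 5 prime ratio of Gapdh, a measure of RNA integrity, was lower in tumor-bearing breast (-0.76 ± 0.17, adjusted p = 0.00055), as was that of actin (-0.39 ± 0.08, adjusted p = 0.00055). The mean Gapdh ratio was 0.03 in tumor-bearing mice and 0.79 in controls, and a higher ratio marks less intact RNA. RNA quality thus differed between the groups, and the breast counts and changes were not corrected for it. Within the earlier batch 3317 genes rose and 3737 fell, and within the later batch 5097 rose and 5123 fell. Without the pair as a block (no replicate block) 5196 genes rose and 5594 fell.

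In the liver, neutrophil granule genes and acute phase genes rose and the fatty acid oxidation and cytochrome P450 lists fell. With an estimated correlation the neutrophil list kept its call, and the acute phase (adjusted p = 0.178), fatty acid oxidation (adjusted p = 0.52) and P450 (adjusted p = 0.592) lists did not. Prtn3, a serine protease of neutrophil granules, rose 53.8-fold (5.75 ± 0.12, higher in 25 of 25 pairs, adjusted p = 1.78e-23), and the calprotectin subunit genes S100a8 (5.25 ± 0.23) and S100a9 (5.03 ± 0.20) rose 38-fold and 32.6-fold. Lcn2 (4.17 ± 0.20), which encodes an iron-siderophore binding protein, rose 18-fold, and Ngp (4.01 ± 0.26), Chil3 (3.06 ± 0.32), Armcx4 (4.12 ± 0.12) and Cyb561 (3.83 ± 0.19) rose as well, with the acute phase genes Saa2 (3.54 ± 0.23) and Orm2 (3.17 ± 0.21). Cyp4a14 (-4.63 ± 0.25), a PPAR alpha target, had the largest fall and was lower in 25 of 25 pairs, as was the acyl-CoA thioesterase gene Acot1 (-3.06 ± 0.18). Of the 18194 genes, 1436 rose and 415 fell, and without the outlying arrays (23 pairs) 2485 rose and 3028 fell.

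Of the 18 measured neutrophil genes, 15 rose (17 adjusted over the list alone, list mean 2.26 ± 0.17, adjusted p = 7.3e-35, and adjusted p = 0.0167 with an estimated correlation), and the list mean was higher in 25 of 25 pairs. Acute phase genes rose in 20 of 27 and fell in 1 (26 and 1 adjusted over the list alone, list mean 1.27 ± 0.17, adjusted p = 9.97e-27, and adjusted p = 0.178 with an estimated correlation). Socs3 (3.02 ± 0.18), a feedback inhibitor of IL-6 signalling, was among the members that rose, and the member that fell was Hamp (-1.15 ± 0.30), which encodes the iron-regulating hormone hepcidin and was chosen after its value was seen. Chemokine and cytokine genes rose in 8 of 26 (9 adjusted over the list alone, list mean 0.40 ± 0.04, adjusted p = 8.72e-05, and adjusted p = 0.0167 with an estimated correlation). The neutrophil attractant gene Cxcl1 (3.05 ± 0.16), Il33 (1.37 ± 0.11) and Cxcl13 (1.28 ± 0.14) rose. Extracellular matrix genes rose in 14 of 24 (16 adjusted over the list alone, list mean 0.61 ± 0.07, adjusted p = 7.85e-12, and adjusted p = 0.0265 with an estimated correlation). The collagen genes Col5a2 (1.72 ± 0.14) and Col4a1 (1.10 ± 0.12) and the matrix protein gene Postn (1.00 ± 0.12) rose. Cell cycle genes rose in 16 of 27 (21 adjusted over the list alone, list mean 0.56 ± 0.09, adjusted p = 1.72e-13, and adjusted p = 0.17 with an estimated correlation). Mcm6 (1.37 ± 0.23), Ccnb2 (0.98 ± 0.14) and Nusap1 (0.80 ± 0.08) rose. Endothelial genes rose in 6 of 14 (11 adjusted over the list alone, adjusted p = 8.66e-07, and adjusted p = 0.391 with an estimated correlation). Plvap (1.14 ± 0.18) and Emcn (0.59 ± 0.10) rose. Monocyte and macrophage genes rose in 4 of 20 (10 adjusted over the list alone, adjusted p = 2.29e-05, and adjusted p = 0.488 with an estimated correlation). The scavenger receptor genes Msr1 (0.83 ± 0.13) and Cd163 (0.71 ± 0.15) rose. Megakaryocyte and platelet genes rose in 6 of 12 (7 adjusted over the list alone, adjusted p = 0.000129, and adjusted p = 0.16 with an estimated correlation). Ppbp (0.96 ± 0.11) and Itgb3 (0.69 ± 0.08) rose.

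Haematopoietic progenitor genes rose in 4 of 14 members (5 adjusted over the list alone, adjusted p = 0.03, and adjusted p = 0.178 with an estimated correlation). Kit (0.87 ± 0.10) and Cd34 (0.90 ± 0.14) rose. That list's mean was 0.21 ± 0.03, and it did not pass after quantile normalization (mean 0.14) or with genes under the median level left out (mean 0.14). Plasma cell genes rose in 5 of 11 (5 adjusted over the list alone, adjusted p = 0.0017, and adjusted p = 0.178 with an estimated correlation), with Jchain (0.86 ± 0.16), the joining chain of secreted antibodies, and Fkbp11 (1.23 ± 0.17), whose change was -0.09 once probe sets named _x_at or _s_at were left out. ER stress and amino acid response genes rose in 4 of 17 (6 adjusted over the list alone, adjusted p = 0.000129, and adjusted p = 0.436 with an estimated correlation). Chac1 (1.43 ± 0.14) and Sdf2l1 (0.92 ± 0.20) rose. Fatty acid oxidation and PPAR alpha target genes fell in 5 of 16 and rose in 1 (6 and 1 adjusted over the list alone, list mean -0.63 ± 0.16, adjusted p = 0.000114, and adjusted p = 0.52 with an estimated correlation), with Acot2 (-0.81 ± 0.13) lower beside Cyp4a14 and Acot1. Without the outlying arrays 12 of 16 fell and 1 rose (list mean -0.80 ± 0.07, adjusted p = 1.55e-09). Cytochrome P450 and bile acid genes fell in 5 of 18 (6 adjusted over the list alone, adjusted p = 0.00031, and adjusted p = 0.592 with an estimated correlation). Cyp7b1 (-1.25 ± 0.21) and Cyp2c38 (-0.70 ± 0.14) fell. Their list mean was -0.41 ± 0.19 in all pairs (sign-flip adjusted p = 0.0553) and -0.62 ± 0.06 without the outlying arrays, where 14 of 18 fell. It was -0.13 in the earlier batch, where it did not pass, and -0.59 in the later batch. Fatty acid synthesis genes fell in 1 of 15 members in all pairs (list mean -0.21 ± 0.21, adjusted p = 0.153) and in 10 without the outlying arrays (list mean -0.45 ± 0.07, adjusted p = 1.59e-05). Cholesterol synthesis genes went from 0 of 18 lower (adjusted p = 0.934) to 7 (adjusted p = 0.0115) without those arrays, and circadian clock genes from 0 of 17 lower (adjusted p = 0.408) to 8 (adjusted p = 0.0241). Members that rose went from 4 to 8 for monocytes and macrophages, from 6 to 10 for endothelium and from 4 to 8 for ER stress. Other genes with large falls were Gsta2 (-2.55 ± 0.19), a glutathione transferase, Acot3 (-2.48 ± 0.33), Ugt2b37 (-2.42 ± 0.30), Pctp (-2.19 ± 0.18), Cyp17a1 (-2.11 ± 0.27), Cyp2g1 (-1.78 ± 0.26) and Akr1c19 (-1.65 ± 0.20), beside Serpinb1a (-1.77 ± 0.23), an inhibitor of neutrophil proteases. Of the hepatocyte marker genes 1 of 13 fell and the list did not pass (adjusted p = 0.808), with 6 lower and 1 higher without the outlying arrays (adjusted p = 0.341).

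Of the remaining lists that passed in liver, 5 did not pass without the outlying arrays. Immediate early and heat shock genes rose in 6 of 19 members and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.00468, and adjusted p = 0.436 with an estimated correlation, adjusted p = 0.153 without those arrays). Btg2 (1.70 ± 0.16), Junb (1.38 ± 0.16) and Fos (1.11 ± 0.15) rose. Interferon response genes rose in 6 of 20 (9 higher and 2 lower adjusted over the list alone, adjusted p = 0.0139, and adjusted p = 0.646 with an estimated correlation, adjusted p = 0.0546 without those arrays). Oas1a (0.80 ± 0.11) rose. Glucocorticoid-responsive genes rose in 3 of 13 (3 adjusted over the list alone, adjusted p = 0.0186, and adjusted p = 0.579 with an estimated correlation, adjusted p = 0.186 without those arrays). Cdkn1a (0.76 ± 0.14) rose. NK and cytotoxic genes fell in 3 of 13 (4 adjusted over the list alone, adjusted p = 0.00109, and adjusted p = 0.391 with an estimated correlation, adjusted p = 0.0668 without those arrays). Gzmb (-0.52 ± 0.13) fell. Keratinocyte genes fell in 1 of 14, Sbsn (-0.28 ± 0.07) (1 adjusted over the list alone, adjusted p = 0.0412, and adjusted p = 0.545 with an estimated correlation, adjusted p = 0.672 without those arrays). With genes under the median level left out, the interferon (0.09), keratinocyte (-0.21) and glucocorticoid (0.31) lists did not pass. The interferon and keratinocyte lists did not pass the sign-flip test either (adjusted p = 0.487 and adjusted p = 0.0934). In the earlier batch alone the NK (-0.11), progenitor (0.15) and megakaryocyte (0.25) lists did not pass, against -0.24, 0.25 and 0.39 in the later batch. In the later batch alone the glucocorticoid (0.08), immediate early (0.16), interferon (-0.01) and keratinocyte (-0.07) lists did not pass, against 0.63, 0.57, 0.31 and -0.17 in the earlier batch. Within the earlier batch 85 genes rose and 10 fell, and within the later batch 2209 rose and 2120 fell. Without a replicate block 1334 genes rose and 381 fell.

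**Figure D2:**
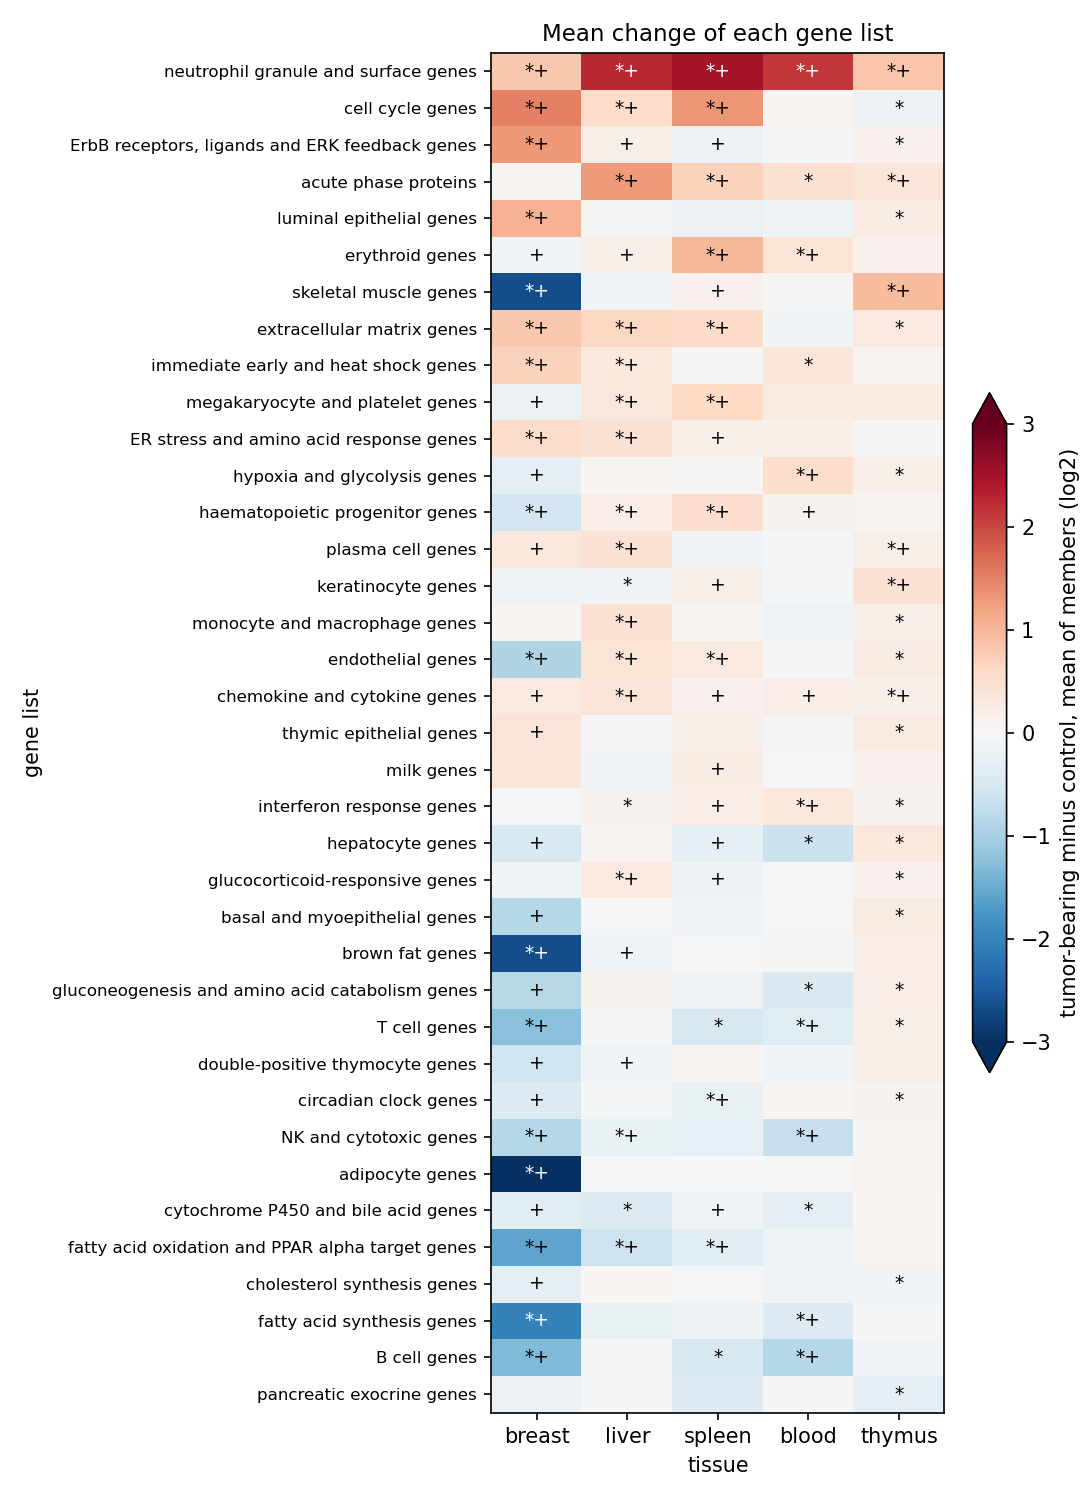
Mean log2 change (tumor-bearing minus control, 25 pairs per tissue) of the 37 gene lists, with rows as lists, columns as tissues and the colour scale limited to changes of 3 in size, where * marks lists that passed camera with the preset correlation and + lists whose mean passed the sign-flip test. The neutrophil list is higher in all 5 tissues, between 0.81 in breast and 2.48 in spleen, and the adipocyte list in breast (-3.19) lies beyond the scale.

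In the spleen, neutrophil, cell cycle and erythroid genes rose, and the B cell and T cell lists fell, with fewer called members in all pairs than without the outlying arrays. None of these passed with an estimated correlation (adjusted p of 0.178 or more), and the B cell and T cell lists did not pass the sign-flip test either (adjusted p = 0.143 and adjusted p = 0.215). The genes with the largest rises included Stfa2l1 (3.83 ± 0.21), a neutrophil stefin that rose 14.2-fold, the neutrophil surface gene Cd177 (3.79 ± 0.27), the primary granule protease genes Ctsg (3.44 ± 0.28) and Prtn3 (3.27 ± 0.25), the neutrophil collagenase gene Mmp8 (3.20 ± 0.25), the haptoglobin gene Hp (3.52 ± 0.20), Slfn4 (3.70 ± 0.22), Chil1 (3.37 ± 0.22) and Ceacam10 (3.29 ± 0.22). The falls were smaller, led by Igfbp5 (-1.76 ± 0.20), an insulin-like growth factor binding protein, Efr3b (-1.72 ± 0.18), Hepacam2 (-1.46 ± 0.10) and Errfi1 (-1.37 ± 0.21), an inhibitor of ErbB receptors, with Fmo1 (-1.35 ± 0.25), Ubd (-1.33 ± 0.33), Cpm (-1.32 ± 0.10) and Sbk1 (-1.31 ± 0.10). Of 18194 genes, 4081 rose and 3327 fell (5371 and 4847 in the 23 pairs without the outlying arrays).

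All 18 measured neutrophil genes rose (18 adjusted over the list alone, list mean 2.48 ± 0.21, adjusted p = 3.16e-16, and adjusted p = 0.178 with an estimated correlation). The collagenase gene Mmp9 (3.01 ± 0.21), the G-CSF receptor gene Csf3r (2.68 ± 0.18) and the chemokine receptor gene Cxcr2 (2.24 ± 0.16) rose. All 27 cell cycle genes rose (27 adjusted over the list alone, list mean 1.31 ± 0.21, adjusted p = 1.77e-12, and adjusted p = 0.458 with an estimated correlation), with Ttk (1.63 ± 0.18), Bub1b (1.59 ± 0.19) and Tyms (1.20 ± 0.11) each higher in 25 of 25 pairs. Erythroid genes rose in 23 of 25 (23 adjusted over the list alone, list mean 0.99 ± 0.18, adjusted p = 3.55e-09, and adjusted p = 0.488 with an estimated correlation). The red cell membrane gene Ank1 (1.31 ± 0.16), the transferrin receptor gene Tfrc (0.95 ± 0.12) and Tspo2 (0.94 ± 0.10) rose. Megakaryocyte and platelet genes rose in 11 of 12 (11 adjusted over the list alone, list mean 0.59 ± 0.17, adjusted p = 0.00203, and adjusted p = 0.621 with an estimated correlation, and adjusted p = 0.0706 with no replicate block). Gp9 (0.70 ± 0.14) and Gp6 (0.42 ± 0.08) rose. Haematopoietic progenitor genes rose in 7 of 14 (8 adjusted over the list alone, adjusted p = 0.0267, and adjusted p = 0.391 with an estimated correlation). Gfi1b (1.04 ± 0.18), Erg (0.82 ± 0.09) and Cd34 (0.80 ± 0.10) rose. Extracellular matrix genes rose in 17 of 24 and fell in 1 (18 and 1 adjusted over the list alone, list mean 0.57 ± 0.05, adjusted p = 4.29e-07, and adjusted p = 0.178 with an estimated correlation). Vcan (1.61 ± 0.14), Timp1 (1.34 ± 0.10) and the fibronectin gene Fn1 (0.90 ± 0.07) rose. Acute phase genes rose in 11 of 27 and fell in 1 (11 and 1 adjusted over the list alone, list mean 0.69 ± 0.05, adjusted p = 0.00145, and adjusted p = 0.178 with an estimated correlation). Steap4 (2.49 ± 0.15), Cd14 (1.02 ± 0.08) and Lcn2 (2.47) rose. Whether these members rose with neutrophils in the spleen was not tested. Endothelial genes rose in 9 of 14 and fell in 1 (9 and 1 adjusted over the list alone, adjusted p = 0.0147, and adjusted p = 0.592 with an estimated correlation). Tie1 (0.78 ± 0.10) and Cdh5 (0.64 ± 0.07) rose.

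B cell genes fell in 7 of 16 members (7 adjusted over the list alone, list mean -0.49 ± 0.27, adjusted p = 0.0158, and adjusted p = 0.761 with an estimated correlation), with Fcer2a (-1.26 ± 0.28) and Vpreb3 (-0.95 ± 0.22), and T cell genes in 3 of 17 (3 adjusted over the list alone, list mean -0.49 ± 0.31, adjusted p = 0.0312, and adjusted p = 0.777 with an estimated correlation), with Lef1 (-0.71 ± 0.24) and Cd3e (-0.51 ± 0.15). Without the outlying arrays 16 of 16 B cell genes fell (list mean -0.85 ± 0.08, adjusted p = 5.6e-10), as did 17 of 17 T cell genes (list mean -0.91 ± 0.07, adjusted p = 2.81e-12). NK and cytotoxic genes went from 5 of 13 lower (adjusted p = 0.101) to 10 (adjusted p = 0.000771) without those arrays, and progenitor genes from 7 higher to 11. Among those arrays, spleen controls 13 and 21 had mean kidney marker levels of 12.1 and 11.7, against a median of 5.36 over spleen arrays. The array labelled spleen tumor-bearing 21 is among them too. It correlated more closely with the median thymus array (0.98) than with the median spleen array (0.91). By the measure that defined the outlying arrays, its correlation with the median spleen array was 0.928. The B cell and T cell list means were -0.83 and -0.77 in the earlier batch and -0.26 and -0.30 in the later batch, where neither passed. Circadian clock genes fell in 9 of 17 and rose in 1 (9 and 1 adjusted over the list alone, adjusted p = 0.00364, and adjusted p = 0.491 with an estimated correlation). Dbp (-0.98 ± 0.10), Nr1d2 (-0.59 ± 0.06) and Clock (-0.41 ± 0.04) fell. Fatty acid oxidation genes fell in 2 of 16 (2 adjusted over the list alone, adjusted p = 0.0372, and adjusted p = 0.721 with an estimated correlation), with Pdk4 (-1.11 ± 0.25) and Acot2 (-0.51 ± 0.05), and the list did not pass with no replicate block (adjusted p = 0.0647), without the outlying arrays (adjusted p = 0.185) or with genes under the median level left out (mean -0.18). Its mean was -0.16 in the earlier batch, where it did not pass, and -0.44 in the later batch. The T cell (mean -0.48) and endothelial (mean 0.27) lists did not pass with genes under the median level left out either, with means of -0.49 and 0.28 over all genes. The Gapdh 3 prime to 5 prime ratio was higher in tumor-bearing spleen (0.12 ± 0.05, adjusted p = 0.0442), and the spleen values were not corrected for it. Within the earlier batch 4002 genes rose and 3870 fell, within the later batch 2931 rose and 1828 fell, and without a replicate block 3761 rose and 2910 fell.

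In blood cells, the neutrophil list rose and the B cell and NK lists fell. With an estimated correlation the neutrophil list kept its call, and the B cell (adjusted p = 0.178) and NK (adjusted p = 0.391) lists did not. Ngp (4.89 ± 0.33) rose 29.6-fold and Lcn2 (4.83 ± 0.39) rose 28.4-fold, with the lactoferrin gene Ltf (4.32 ± 0.34), the cathelicidin gene Camp (3.77 ± 0.29), Mmp8 (3.79 ± 0.27), Steap4 (4.77 ± 0.25), Ifitm1 (4.18 ± 0.20), Stfa2l1 (4.13 ± 0.19) and the arginase gene Arg2 (3.61 ± 0.19). The largest falls were in Ighv14-2 (-2.37 ± 0.25), an immunoglobulin heavy chain segment, the class II antigen presentation gene H2-Ob (-1.71 ± 0.28), the interferon-induced GTPase gene Iigp1 (-1.59 ± 0.37), the IgM receptor gene Fcmr (-1.43 ± 0.19), the stearoyl-CoA desaturase gene Scd1 (-1.41 ± 0.25), Cnn3 (-1.34 ± 0.23), Bank1 (-1.24 ± 0.26), Fcer2a (-1.22 ± 0.18) and the lymphocyte activation gene Cd69 (-1.15 ± 0.19). Of 18194 genes, 1576 rose and 776 fell, against 1859 and 2174 without the outlying arrays (21 pairs), 1468 and 1166 after quantile normalization and 1569 and 468 after median centring. Hepatocyte genes lay more than 3 above their median of 5.19 in 6 blood arrays (5 control and 1 tumor-bearing, up to 9.80), and in the 19 pairs without these arrays 1575 genes rose and 362 fell.

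Neutrophil genes rose in 12 of 18 members (12 adjusted over the list alone, list mean 2.12 ± 0.15, adjusted p = 2.17e-23, and adjusted p = 0.00766 with an estimated correlation), and Cxcr2 (2.99 ± 0.16) was among them. B cell genes fell in 14 of 16 (15 adjusted over the list alone, list mean -0.86 ± 0.16, adjusted p = 7.85e-12, and adjusted p = 0.178 with an estimated correlation). The complement receptor gene Cr2 (-0.78 ± 0.12) and Cd72 (-0.47 ± 0.08) fell. NK and cytotoxic genes fell in 12 of 13 (13 adjusted over the list alone, list mean -0.68 ± 0.16, adjusted p = 9.53e-09, and adjusted p = 0.391 with an estimated correlation). The T-bet gene Tbx21 (-0.90 ± 0.18), Prf1 (-0.83 ± 0.17) and Klrg1 (-0.53 ± 0.10) fell. T cell genes fell in 7 of 17 (11 adjusted over the list alone, list mean -0.37 ± 0.14, adjusted p = 2.63e-05, and adjusted p = 0.548 with an estimated correlation). Cd28 (-0.82 ± 0.19), Lef1 (-0.56 ± 0.13) and Cd3e (-0.37 ± 0.09) fell. Hypoxia and glycolysis genes rose in 10 of 20 (11 adjusted over the list alone, list mean 0.53 ± 0.12, adjusted p = 3.16e-07, and adjusted p = 0.391 with an estimated correlation). The glucose transporter gene Slc2a1 (2.02 ± 0.21), Egln3 (1.30 ± 0.17) and the hexokinase gene Hk2 (1.03 ± 0.14) rose. Erythroid genes rose in 11 of 25 (14 adjusted over the list alone, list mean 0.41 ± 0.10, adjusted p = 6.69e-07, and adjusted p = 0.426 with an estimated correlation). Epb42 (1.28 ± 0.21) and the heme synthesis gene Urod (0.95 ± 0.15) rose. Interferon response genes rose in 8 of 20 and fell in 1 (9 and 1 adjusted over the list alone, adjusted p = 0.00162, and adjusted p = 0.488 with an estimated correlation). Oasl2 (3.39 ± 0.20) and Oas2 (1.15 ± 0.15) rose. Fatty acid synthesis genes fell in 3 of 15 (4 adjusted over the list alone, adjusted p = 0.00845, and adjusted p = 0.579 with an estimated correlation), with Elovl6 (-0.59 ± 0.16) beside Scd1. That list mean was -0.04 in the earlier batch and -0.61 in the later batch. The list, Scd1 (-0.68) and Elovl6 (-0.38) did not pass in the earlier batch alone. Without the arrays rich in hepatocyte transcripts the list mean was -0.13 and did not pass (adjusted p = 0.586), nor did Elovl6 (-0.53) or Cd3e (-0.34). Without the outlying arrays 5 of 15 fatty acid synthesis genes and 13 of 17 T cell genes fell.

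Acute phase genes rose in 7 of 27 members (7 adjusted over the list alone, adjusted p = 0.0175, and adjusted p = 0.721 with an estimated correlation). Socs3 (2.70 ± 0.22) and Lcn2 (4.83) were among them, and whether they rose with neutrophils was not tested. The camera test of that list was upward and its mean was 0.46 ± 0.21, while its median member was at -0.16. In the 19 pairs without the arrays rich in hepatocyte transcripts the list mean was 0.82 (adjusted p = 4.72e-06, 7 members higher and 0 lower). The acute phase list did not pass in the later batch alone (list mean 0.33). Another 4 lists passed in blood but not without the outlying arrays. They were gluconeogenesis and amino acid catabolism (1 of 13 lower, 0 adjusted over the list alone, adjusted p = 0.00647, and adjusted p = 0.592 with an estimated correlation, adjusted p = 0.0519 without those arrays), with Tdo2 (-0.55 ± 0.18) no longer called without them, the hepatocyte list (1 of 13 lower, 0 adjusted over the list alone, adjusted p = 0.0117, and adjusted p = 0.72 with an estimated correlation, adjusted p = 0.154 without those arrays), the cytochrome P450 list and the immediate early list. Of the P450 genes limma called 0 of 18, with 0 adjusted over the list alone (adjusted p = 0.0281, and adjusted p = 0.683 with an estimated correlation, adjusted p = 0.221 without those arrays). Immediate early and heat shock genes rose in 4 of 19 (5 adjusted over the list alone, adjusted p = 0.0163, and adjusted p = 0.682 with an estimated correlation, adjusted p = 0.192 without those arrays, and adjusted p = 0.0532 with no replicate block). Ier3 (1.64 ± 0.26) and Zfp36 (1.23 ± 0.24) rose. Monocyte and macrophage genes (adjusted p = 0.773), platelet genes (adjusted p = 0.171) and cell cycle genes (adjusted p = 0.556) did not pass as lists. Without the arrays rich in hepatocyte transcripts the hepatocyte (-0.03), gluconeogenesis (-0.11) and P450 (-0.08) lists did not pass, against -0.64, -0.43 and -0.28 in all pairs, and Tdo2 (-0.23) was not called. With genes under the median level left out, the gluconeogenesis (-0.40), P450 (-0.40) and immediate early (0.44) lists did not pass. The hepatocyte, gluconeogenesis and P450 lists, the acute phase list and the immediate early list did not pass the sign-flip test (adjusted p between 0.0554 and 0.179). The P450 (-0.06), gluconeogenesis (-0.08) and hepatocyte (-0.17) lists did not pass in the earlier batch alone, against -0.43, -0.66 and -0.95 in the later batch, and the immediate early list (0.15) did not pass in the later batch alone, against 0.70 in the earlier batch. Within the earlier batch 303 genes rose and 14 fell, within the later batch 1119 rose and 1002 fell, and without a replicate block 1511 rose and 607 fell.

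**Figure D3:**
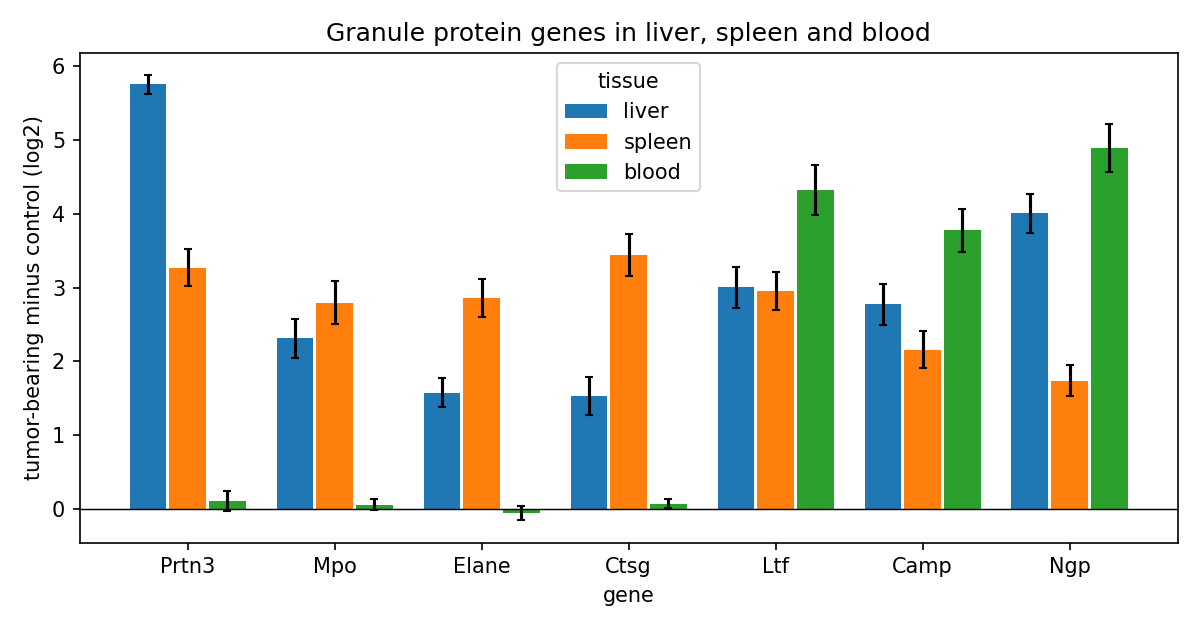
Log2 change (tumor-bearing minus control, bars as means and whiskers as SE over 25 pairs) of 4 primary granule genes and 3 secondary granule genes of neutrophils in liver, spleen and blood. Mpo, Elane and Ctsg are higher by 1.53 to 3.44 in liver and spleen and lie between -0.06 and 0.07 in blood, where Ltf, Camp and Ngp are higher by 3.77 to 4.89.

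In the thymus the genes called were S100a9 and S100a8, which rose 4.62-fold (2.21 ± 0.37, higher in 22 of 25 pairs) and 3.67-fold (1.88 ± 0.31, higher in 23 of 25 pairs), both at adjusted p = 0.0191. Lcn2 (1.52 ± 0.31) had adjusted p = 0.153, was higher in 22 of 25 pairs and passed without the outlying arrays (1.77). Limma called 0 genes lower at an adjusted p under 0.05, with 757 genes of both directions at an unadjusted p under 0.05, and a plain paired t-test called 0 in either direction (718 unadjusted). Without the pairs on another plate or with differing date parts (23 pairs) limma called 0 as well (585 unadjusted). Without the outlying arrays (18 pairs) 8 genes rose and 0 fell (1130 at an unadjusted p under 0.05). Neutrophil genes rose in 2 of 18 members (7 adjusted over the list alone, list mean 0.83 ± 0.29, adjusted p = 1.28e-15, and adjusted p = 0.179 with an estimated correlation, sign-flip adjusted p = 0.0196). That list mean was 0.22 in the earlier batch, where it did not pass, and 1.23 in the later batch. Acute phase genes had 0 of 27 called by limma and 3 higher adjusted over the list alone (list mean 0.35 ± 0.12, adjusted p = 1.35e-09, and adjusted p = 0.17 with an estimated correlation). Skeletal muscle genes had 0 of 17 called and 9 higher adjusted over the list alone (list mean 0.96 ± 0.37, adjusted p = 3.1e-15, and adjusted p = 0.178 with an estimated correlation). The list mean was higher in 15 of 25 pairs and was 0.85 ± 0.41 without the outlying arrays (adjusted p = 2.49e-08). Skeletal muscle genes lay more than 3 above their median of 7.80 in 5 thymus arrays (4 tumor-bearing and 1 control, up to 12.8), and heart markers in 8 (4 of each group).

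Camera passed 23 of the 37 lists in thymus, 20 upward and 3 downward, while the sign-flip test passed 6 (the neutrophil, skeletal muscle, acute phase, keratinocyte, chemokine and plasma cell lists). With an estimated correlation camera passed 0 of them (8 at an unadjusted p under 0.05), with adjusted p between 0.0827 and 0.777. Keratinocyte genes had 3 of 14 higher adjusted over the list alone and 0 over all genes (list mean 0.42 ± 0.17, adjusted p = 1.46e-05, and adjusted p = 0.313 with an estimated correlation), and chemokine and cytokine genes had 4 of 26 and 0 (list mean 0.16 ± 0.04, adjusted p = 7.13e-05, and adjusted p = 0.0827 with an estimated correlation). The cell cycle list (-0.15 ± 0.13, adjusted p = 3.16e-07, and adjusted p = 0.539 with an estimated correlation) was among the 3 downward lists. The T cell list mean was 0.18 ± 0.26 (adjusted p = 0.0377, and adjusted p = 0.777 with an estimated correlation), and without the outlying arrays it was -0.11 ± 0.07 with the test downward. The thymic epithelial list mean was 0.28 ± 0.22 (adjusted p = 0.00204, and adjusted p = 0.579 with an estimated correlation) and -0.00 ± 0.05 without those arrays. Within the earlier batch limma called 0 genes (326 at an unadjusted p under 0.05), and within the later batch 12 rose. Without a replicate block the count was again 2.

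Across tissues, S100a8 and S100a9 rose in all 5, and Lcn2, Cebpd, Socs3, Pglyrp1, Fosl2, Mmp8, Pgm2 and Csf3r rose in breast, liver, spleen and blood. Cebpd, a transcription factor of the acute phase response, rose by 1.13 ± 0.13 in breast, 1.36 ± 0.11 in liver, 1.43 ± 0.11 in spleen and 2.83 ± 0.21 in blood. Fosl2 rose by 1.08 ± 0.12, 0.72 ± 0.09, 1.40 ± 0.14 and 2.13 ± 0.18 in the same order, and its liver change was 0.28 and not called with the mean of all its probe sets. In breast, liver, spleen and blood together 126 genes were called in the same direction, against 9.41 expected if the calls of each tissue were independent, and 118 of them rose. Spleen and blood shared 872 genes that rose against 354 expected (one-sided hypergeometric p = 2.14e-196) and 363 that fell against 142 expected. Liver and blood shared 338 genes that rose against 124 expected, and their 22 shared genes that fell did not exceed the 17.7 expected (p = 0.174). The expected counts and the hypergeometric p treat genes and tissues as independent. The tissues are assumed to come from the same mice and many genes move together, so a small p here overstates the evidence. With an estimated correlation, camera passed the neutrophil, chemokine and extracellular matrix lists in liver and the neutrophil list in blood, and it passed 0 lists in breast and spleen (1 and 3 at an unadjusted p under 0.05).

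The change of 5298 genes differed between liver, spleen, blood and thymus at an adjusted p under 0.05 (4412 with no replicate block). The median share of values raised to the floor was 13.8% per array in blood, 6.58% in liver and 0% in spleen and thymus. Changes of dim genes can be reduced by the floor in blood and liver, and the offset alternative was not run for this fit. How much of the count rests on that was not tested. The neutrophil list rose more in liver than in breast (breast minus liver -1.45, adjusted p = 4e-05) and this test, which treats the tissues as independent, did not pass between liver and blood (0.13, adjusted p = 0.626), liver and spleen (-0.22, adjusted p = 0.477) or spleen and blood (0.36, adjusted p = 0.229). Within linked mice, a test added after seeing the data, that list rose more in spleen than in blood (0.38 ± 0.15, 18 of 24 mice, adjusted p = 0.0227). Liver minus blood (0.15 ± 0.08, adjusted p = 0.136) and liver minus spleen (-0.22 ± 0.15, adjusted p = 0.22) did not pass there. The erythroid list rose more in spleen than in blood (spleen minus blood 0.57, adjusted p = 0.00973) and the cell cycle list more in spleen than in liver (liver minus spleen -0.76, adjusted p = 0.00081, and -0.48 without the outlying arrays). The acute phase list rose more in liver than in spleen (0.59, adjusted p = 0.00014, and 0.37 without the outlying arrays). Fewer of its members were called in spleen, so its mean need not stand for the same response in both tissues. The hypoxia list rose more in blood than in spleen (spleen minus blood -0.50, adjusted p = 7e-05, and -0.33 without those arrays), and the NK list fell further in blood than in liver (liver minus blood 0.49, adjusted p = 0.0126). All 5 of these differences also passed within linked mice.

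Pairs with a larger neutrophil list change in liver also had a larger change in blood and spleen. Across 24 linked pairs the neutrophil list change in liver correlated with that in blood with r = 0.88 and rho = 0.84 (permutation p = 1e-05 for both, the smallest these permutations can give, adjusted p = 0.00013 over 13 relations). The r was 0.83 without the 2 pairs farthest from the median, 0.91 in the earlier batch and 0.87 in the later batch. Spleen and blood gave r = 0.71 and rho = 0.80 (adjusted p = 0.00065 for r), 0.84 without the 2 farthest pairs, and 0.91 and 0.65 in the batches. Liver and spleen gave r = 0.67 and rho = 0.73 (n = 25, adjusted p = 0.00065 for r), 0.64 without the 2 farthest pairs, and 0.89 and 0.65 in the batches. Liver and thymus gave r = 0.51 and rho = 0.59 (adjusted p = 0.0173 for r), 0.53 without the 2 farthest pairs, and 0.35 and 0.52 in the batches. Breast and liver gave r = -0.00 and rho = -0.11 (adjusted p = 0.988 for r), and spleen with thymus (r = 0.19, adjusted p = 0.646) and blood with thymus (r = 0.33, adjusted p = 0.261) did not pass, while values of the tumor-bearing mice alone gave r = 0.54 and r = 0.55 there, which passed. The erythroid list change correlated between liver and blood (r = 0.69, rho = 0.64, adjusted p = 0.00065 for r, 0.65 without the 2 farthest pairs, 0.57 and 0.81 in the batches). Liver with spleen gave r = 0.08, and 0.01 without the 2 farthest pairs. Spleen with blood gave r = 0.01, and 0.27 without its 2 farthest pairs.

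**Figure D4:**
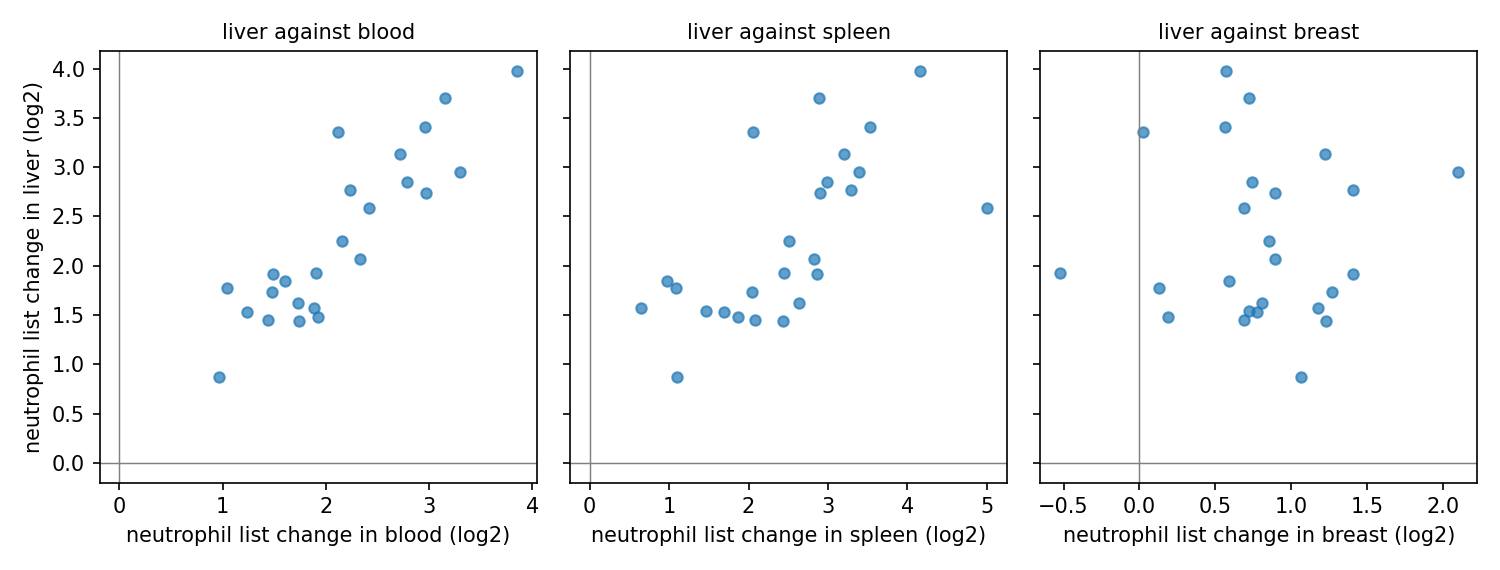
Within-pair log2 change of the neutrophil list in liver (vertical axis) against that in blood, spleen and breast (horizontal axes), where each point is a linked pair of mice. The points rise together for blood (r = 0.88, n = 24) and spleen (r = 0.67, n = 25) and not for breast (r = -0.00, n = 25).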

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

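The tests of blood left in tissues, of values near the floor, of both Prtn3 explanations, of dilution and of RNA quality were chosen only after the results were seen. The immature granulocyte test and the splits were chosen before.

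The first pattern is that the primary granule genes Mpo, Elane and Ctsg were higher in liver and spleen and not in blood, although secondary granule genes rose in blood. Blood left in the tissues stays open. Within arrays of tumor-bearing mice the primary minus secondary granule level was 4.11 higher in liver than in blood (95% interval 3.50 to 4.72) and 4.55 higher in spleen (3.93 to 5.17), and a first test of the within-pair changes gave 2.85 for liver minus blood (2.10 to 3.59), but both rest on dim blood values. Values near the floor in blood stay open too, because 72.7% of the 150 blood values of these genes lay under the median probe set of their own array, although the first criterion, values at the floor itself (1.33%), would have excluded this and was replaced once so many dim values were seen. Immature granulocytes in the tissue may account for the pattern. The link of the cell cycle list to these genes across liver pairs lay between the bounds set beforehand and did not decide (Spearman rho = 0.33, p = 0.103, Pearson r = 0.37 and 0.13 without the 2 farthest pairs, rho = 0.25 and 0.36 in the earlier and later batch). Without the outlying arrays, an alternative added after seeing the data, the liver rho was 0.41, just past the upper bound. In spleen rho was 0.47 (p = 0.0203, 0.78 and 0.33 in the batches) and 0.59 without the outlying arrays.

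The second pattern is that Prtn3 rose in liver by 5.75, more than Mpo (2.31), Elane (1.58) and Ctsg (1.53). Granulocyte precursors with the gene ratios seen in spleen are argued against, since Prtn3 minus the mean of the other genes was 4.12 in tumor-bearing liver and 0.33 in tumor-bearing spleen, a difference of 3.79 (95% interval 3.36 to 4.22), taken as a difference of differences because the tissues look scaled separately. Signal of another transcript on the Prtn3 probe set stays open, because only 1 probe set carries this symbol alone. Expression of Prtn3 in liver cells themselves was not tested and stays open.

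The third pattern is that B cell and NK genes fell in blood. Whether dilution by neutrophil RNA is the whole cause could not be told, because T cell genes fell too and the wider comparison includes lists above 0. B cell and NK genes fell further than the mean of the T cell, monocyte, platelet and erythroid lists by -0.87 (95% interval -1.09 to -0.65). That mean was chosen with the values of its lists in view. Its erythroid (0.45 ± 0.11) and platelet (0.23 ± 0.26) lists lay above 0, which widens the gap. The T cell list itself was at -0.38 ± 0.14. A first test, of B cell genes against T cell genes alone, gave -0.58 (-0.94 to -0.21). B cell genes thus fell further than T cell genes, but the test did not decide by its bound of -0.3. B cell genes against monocyte and macrophage genes alone gave -0.83 (-1.15 to -0.51). RNA quality as the whole cause is argued against, since the change at no within-pair difference in the Gapdh and actin ratios was -0.92 (-1.23 to -0.62). The first test of RNA quality was a rank correlation of the B cell list change with the Gapdh ratio change, fixed beforehand. It gave rho = 0.34 (p = 0.093), between its bounds, and did not decide. Pearson's r for the same relation was 0.57 (permutation p = 0.00326), and 0.17 without the 2 farthest pairs. Both replacements were chosen afterwards. A lower number of B and NK cells relative to other blood cells in tumor-bearing mice may be a candidate explanation, as a hypothesis found and tested on the same data. Dilution as the whole cause and a lower expression per cell stay open.

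The change differed between liver, spleen, blood and thymus for 5298 genes by the interaction test, while the share of values raised to the floor also differed between these tissues. List changes differed, of those passing in at least 1 tissue of each comparison, for 19 lists between breast and liver, 17 between breast and spleen, 16 between breast and blood and 23 between breast and thymus. They differed for 10 lists between liver and spleen, 12 between liver and blood, 12 between liver and thymus, 7 between spleen and blood, 11 between spleen and thymus and 9 between blood and thymus.

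Of the 10143 probe sets with no gene symbol or several, 51 control probe sets of the array were left out. Among the other 10092, none of them used for the named genes, 4722 were called in breast, 413 in liver, 3064 in spleen, 641 in blood and 3 in thymus. They were tested in the same way and are otherwise not analysed here.

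Swapping labels within pairs at random tested whether chance could give as many called genes. In each tissue 1 of 100 splits, the real one, gave as many, so chance is excluded as the cause of the counts in breast, liver, spleen and blood. In thymus the count itself is small and fell to 0 by the plain paired t-test, at an adjusted p under 0.01 and without pairs on another plate or with differing date parts, so less rests on it there. The real count was 11329 in breast against 8011 in the highest other split, 7408 against 2540 in spleen, 1851 against 0 in liver, 2352 against 1 in blood and 2 against 0 in thymus. The highest other splits of breast and spleen left 20 of 25 pairs as in the real split or its mirror. For the difference between the 4 tissues, 5298 genes compare with 13 in the highest other of 100 splits, and 1 split, the real one, gave as many.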

How the results depend on the processing

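The leaving out of outlying arrays, the leaving out of breast pairs 1 and 2 and of blood arrays rich in hepatocyte transcripts, the sign-flip test and the test within linked mice were chosen only after the results were seen, and all other alternatives were chosen before. Over all alternatives, 252 values of the main results stayed within their limits, 42 moved and 2 correlations came to pass. Of the values of named genes, 4079 kept direction and side of the threshold, 129 lost the call, 4 gained one and 1 reversed, and of those of the lists, 1182 kept both, 169 lost the call and 6 reversed. Median centring changed none of the 359 values of genes and lists, quantile normalization ended 12 calls and reversed none, and with no replicate block 354 kept their call and 5 lost it. The mean of all Erbb2 probe sets could not be run, since there is 1 such probe set. The cause was not tested for any of the changes below unless stated.

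Counts fell with genes under the median level left out, where fewer genes were tested, to 2996 lower in breast and 215 lower in liver, while 4 rose in thymus. An adjusted p under 0.01, a stricter threshold by construction, left 951 higher and 220 lower in liver, 326 lower in blood and 0 in thymus (757 by limma at an unadjusted p under 0.05). In the earlier batch, with 10 pairs, the counts were 3317 and 3737 in breast, 85 and 10 in liver, 303 and 14 in blood and 0 in thymus (326 unadjusted). In the later batch they were 2209 and 2120 in liver, 1828 lower in spleen and 12 higher in thymus. Array weights gave 3459 and 3674 in liver, 2980 lower in blood and 85 and 4 in thymus. Leaving out the outlying arrays gave 2485 and 3028 in liver, 2174 lower in blood and 8 higher in thymus. In liver and blood both settings raised the counts although the second uses fewer pairs. Without blood arrays rich in hepatocyte transcripts 362 genes were lower in blood. Within linked mice the number of lists that differed changed from 12 to 11 between liver and thymus, from 7 to 8 between spleen and blood and from 11 to 10 between spleen and thymus. Genes lower in blood numbered 1166 after quantile normalization and 468 after median centring. Without pairs on another plate or with differing date parts 261 genes were lower in liver and 0 called in thymus (585 unadjusted). The thymus count was 1 without _x_at and _s_at probe sets, which removes 1 of its genes, and 0 by the plain paired t-test (718 unadjusted).

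With an estimated correlation camera passed 0 lists in breast, 3 in liver, 0 in spleen, 1 in blood and 0 in thymus (1, 9, 3, 2 and 8 at an unadjusted p under 0.05). The sign-flip test, which asks a different question, passed 30 in breast, 20 in spleen and 6 in thymus. Reversed list means were those of T cell and B cell genes in breast in the earlier batch (0.065 and 0.061) and, in thymus, of T cell genes in the later batch (-0.057) and, without outlying arrays, of T cell (-0.11), thymic epithelial (-0.0018) and interferon response genes (-0.030). Fkbp11 in liver reversed to -0.085 without _x_at and _s_at probe sets, where another probe set stands for it. With values of tumor-bearing mice alone the neutrophil list correlation passed for spleen and thymus (r = 0.54) and for blood and thymus (r = 0.55). For arrays, signal over background limits what can be seen: in blood, 72.7% of the values of Mpo, Elane and Ctsg lay under the median probe set.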

Other observations

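The genes named in the next paragraph and the array values after it were chosen only after the results were seen.

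In breast, acute phase genes went both ways. Saa3 (2.76 ± 0.27), which encodes a serum amyloid made outside the liver, and Lbp (2.68 ± 0.23) rose while Orm1 (-4.69 ± 0.38) and Orm3 (-1.38 ± 0.12) fell, and the acute phase list as a whole did not pass (9 of 27 members higher and 8 lower, with 9 and 8 adjusted over the list alone, adjusted p = 0.772). The angiogenic factor gene Vegfa (-1.56 ± 0.12) fell, as did the checkpoint ligand gene Cd274 (-2.17 ± 0.21), while Il1b (2.15 ± 0.20) and the receptor gene Erbb3 (1.54 ± 0.18) rose. The adipocyte and skeletal muscle lists also fell in breast. For Vegfa and Cd274 a smaller share of such cells and a lower expression per cell cannot be told apart. Granzymes went both ways, with Gzmc (2.76 ± 0.30) and Gzmf (3.05 ± 0.43) higher beside Gzmd and Gzme, and Gzma (-1.78 ± 0.19) lower. Milk genes named here also rose, with Wap (1.37 ± 0.33), Lalba (1.11 ± 0.35) and Csn2 (0.90 ± 0.32). In liver, Egfr (1.34 ± 0.21), which encodes the EGF receptor, rose and albumin did not pass (0.04 ± 0.04, adjusted p = 0.609). In spleen the erythroid transcription factor genes Gata1 (1.25 ± 0.18) and Klf1 (1.12 ± 0.25) rose, and Il1b (2.75 ± 0.25) and Prok2 (3.02 ± 0.32) rose in blood.

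Several arrays carried transcripts that other arrays of their label did not. Spleen controls 13 and 21 had Umod, a kidney tubule gene, at 14.3 and 13.5 and Miox at 14.6 and 14.3 (log2), against medians of 4.36 and 4.44 over the other spleen arrays. The array labelled spleen tumor-bearing 21 had Myh6, a heart gene, at 12.7, Scgb1a1, an airway gene, at 13.8 and Rag1 at 12.6. It correlated with the median thymus array at 0.98 and with the median spleen array at 0.91 (0.928 by the measure that defined the outlying arrays). The array labelled thymus control 20 correlated with the median spleen array at 0.99 and with the median thymus array at 0.92 (0.933 by the measure that defined the outlying arrays). Its pancreatic exocrine mean was 12.2. The array labelled thymus control 11 had the steroid synthesis genes Hsd3b1 and Akr1c18 at 14.2 and 14.5 and Inha at 13.2. In breast, the array labelled control 1 had Mmp13 at 10.9 and Erbb2 at 8.64, and the array labelled tumor-bearing 2 had Mmp13 at 3.57 and Erbb2 at 7.39. By the measure that defined the outlying arrays, liver control 2 correlated with the median liver array at 0.333 and blood control 9 with the median blood array at 0.711. Thymus control 2 correlated with the median thymus array at 0.727. In all, 3 spleen arrays and 2 thymus arrays correlated more closely with the median array of another tissue than with that of their own. No array was relabelled, and the source of these transcripts was not tested.

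Pancreatic exocrine genes lay more than 3 above their median in 17 spleen arrays, with no detectable difference between groups (-0.39 ± 0.88, adjusted p = 0.557). Among the marker lists added after the array correlations were seen, the ovary and uterus list was higher in tumor-bearing spleen (0.45 ± 0.04, 24 of 25 pairs, permutation adjusted p = 0.00016), and it holds Ltf, which is also a neutrophil granule gene. The lung list was higher in tumor-bearing spleen (0.23 ± 0.15, 19 of 25 pairs, permutation adjusted p = 0.00888), with a mean of 0.08 ± 0.02 without the outlying arrays.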
